A study of Mus musculus with 8 samples.

How the data were processed

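RNA was sequenced from CT26, a mouse colorectal carcinoma cell line, grown either as transplanted tumours or as cell cultures. Per the labels, the tumours were treated with normal saline or with the drug mLJZD, an abbreviation the labels leave unexpanded, and the cultures received for 48 hours medium with 10% control serum or 10% serum containing mLJZD. Each of the 4 groups has 2 libraries, 8 in all. Per the labels' protocols, total RNA was extracted with a column kit for cells and tissue and libraries were prepared with the VAHTS Universal V10 RNA-seq kit. The labels do not say whether the 2 libraries of a group come from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

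The authors deposited 1 table of raw counts per gene, with 1 column per library. Per the submitters' processing notes, reads were handled with Trim Galore, FastQC 0.12.1, HISAT2 2.2.1, SAMtools 1.14 and featureCounts 2.0.3 on the build GRCm39. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Counts of antisense genes and of the genes they overlap can therefore not be separated, and members of gene families with near-identical copies, such as immunoglobulin V segments, haemoglobin, Hspa1, Gstp and histone genes, may share reads. The mouse strain behind CT26 also differs from the reference strain, which makes the assignment of single V segments uncertain.

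The table holds 56953 Ensembl gene identifiers, of which 28207 had no count in any library. Symbols, gene classes, and the length and GC content of the longest transcript were looked up by identifier in GENCODE M21, an annotation of an earlier mouse build, and no coordinates were taken from it. This named 52029 identifiers. The other 4924 held between 0.343% and 0.596% of the counts of a library and stayed in the tests without a name. Library totals ran from 16594912 to 29363861 counts. At these totals a group floor of 3 counts over its 2 libraries was used for genes absent from a group, and a fold change against such a group is given as a lower bound. Floors cover counting error only.

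Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test, two-sided, with TMM normalization, the filterByExpr filter and Benjamini-Hochberg adjustment over all genes tested, called at an adjusted p under 0.05. Tumours, cultures and the pair of control groups were fitted separately with 4 libraries each. The difference between the effect in tumours and the effect in cultures was tested as an interaction over all 8 libraries. A standard error (SE) is the log2 fold change divided by the square root of F. Levels are CPM, counts scaled to the library total, as mean ± SD with n = 2. An exact permutation test of a single gene cannot pass 0.05 with groups of 2, so single-gene p-values rest on the model fitted across genes.

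The 41 gene lists were fixed before the data were examined, as were the comparisons, the tests and the rule for named genes. The rule names Chek1 and Cenpm in every comparison. It adds the 10 largest changes per direction in each treatment comparison among called genes with a mean of at least 1 CPM in the higher group, no overlap between the libraries of the groups and an established symbol. It adds up to 4 changed members of a list, and the 5 largest changes per direction for the control contrast and for the interaction. Lists with at least 3 tested members were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry's p tests whether the genes of a list move, on balance, in 1 direction, and does not compare the list with other genes. Lists of cell type markers describe RNA in bulk material and name no cell.

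The gene tests, the list tests and the trend removal were tested on counts simulated from the real gene means and library sizes. In the gene tests 200 genes were changed. All genes of a simulated comparison shared 1 dispersion, so the shares below hold for that setting. Other computations were not tested in this way. In the simulated tumours, with 15393 genes tested, edgeR recovered 83.6% of genes changed 1.5-fold, 92.5% at 2-fold and 100% at 4-fold, with 4.66% of calls false. In the simulated cultures, with 13246 genes, it recovered 77.6%, 97.0% and 100%, with 3.17% of calls false. For the interaction, with 15960 genes, it recovered 58.2%, 94.0% and 100%, with 5.08% of calls false, while limma-voom gave 23.1% false calls. In the simulated control contrast, with 15012 genes, the recovered shares were 91.0%, 98.5% and 100%, with 5.39% of calls false. A mitosis list lowered 1.3-fold had an adjusted p of 5.96e-38 with the preset correlation and 0.166 with an estimated one in the simulated tumours, and 1.90e-28 and 0.172 in the simulated cultures. An estimated correlation therefore missed a known shift at this number of libraries. The simulated genes varied independently, whereas list correlations estimated from the data ran up to 0.619 in tumours and 0.984 in cultures. The simulation therefore cannot say whether the preset correlation suits the data.

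A trend with transcript length and GC content was removed, as an alternative chosen after seeing the data, by fitting a smooth curve per library to log2 CPM (natural splines, 5 degrees of freedom each) and entering it as an offset. In simulated cultures that carried only a length trend of 0.5 log2 per doubling, 6483 of 12957 genes were called before removal and 0 after it. With 200 changed genes added, 97.0% of those changed 2-fold were recovered after removal, and 25 of the 205 calls were false.

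The alternatives were DESeq2 1.42.0, limma-voom, RLE, upper-quartile and total-count scaling, no filter and a stricter filter of 5 CPM, a 2-fold threshold, all libraries in a single fit, thinning to the lowest total, a replicate block, and leaving out each library. Where a left-out library leaves an arm with 1 library, that library is assumed to vary like the other group. Replicate numbers are shared across groups in the labels, with nothing to say that they mark shared animals or days. The counts of the 2 libraries of a group differed by more than counting noise, since their chi-square over its degrees of freedom ran from 2.68 to 11.6. This does not show that the libraries come from separate animals or cultures. No library was left out.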

Results

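Gene-level RNA counts were compared between transplanted CT26 tumours given saline or mLJZD and between CT26 cultures given control serum or serum containing mLJZD, with 2 libraries in each of the 4 groups. The title of the series sets an axis of CHEK1, histone H3 acetylation and CENPM as the question; the libraries measure RNA only. Saline tumours had library totals of 19692863 and 19793632 counts and mLJZD tumours of 18324302 and 16594912. Control cultures had 23426845 and 22196014 counts and mLJZD cultures 20439449 and 29363861. The first principal component of log2 CPM held 89.3% of the variance and separated tumours from cultures.

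The genes of the title were measured in every library. Cenpm (ENSMUSG00000068101), which encodes a centromere protein, was lower under mLJZD in both materials. It fell from 32.7 ± 0.60 CPM (SD, n = 2) in saline tumours to 18.4 ± 1.42 CPM in mLJZD tumours, a log2 fold change of -0.79 (SE 0.09, edgeR adjusted p = 5.11e-06). In cultures it fell from 51.5 ± 1.13 CPM to 23.9 ± 0.74 CPM, a log2 fold change of -1.17 (SE 0.09, edgeR adjusted p = 2.00e-07), and of -0.51 (edgeR adjusted p = 0.000602) once the trend with transcript length and GC content described below for the cultures was removed. Chek1 (ENSMUSG00000032113), the checkpoint kinase that acts downstream of ATR, fell in tumours from 23.5 ± 0.51 to 17.9 ± 1.82 CPM, a log2 fold change of -0.36 (SE 0.10, edgeR adjusted p = 0.0125). In cultures Chek1 stood at 26.3 ± 0.67 and 30.2 ± 0.57 CPM, a log2 fold change of 0.15 that did not pass (SE 0.10, edgeR adjusted p = 0.257). The call for Chek1 in tumours was lost with DESeq2 (adjusted p = 0.0644), without saline replicate 1 (0.0542) and without mLJZD replicate 1 (0.135) or 2 (0.0612). The 2 effects differed between the materials in the interaction for Cenpm (log2 0.46, SE 0.12, edgeR adjusted p = 0.00635) and for Chek1 (log2 -0.42, SE 0.14, edgeR adjusted p = 0.0198). Neither difference passed with the length and GC trend removed (edgeR adjusted p = 0.378 and 0.168), and neither did without tumour mLJZD replicate 1 (0.0652 for Cenpm and 0.0944 for Chek1). The difference for Cenpm also ended with library totals only (0.0816) and with no filter on low counts (0.0801), and that for Chek1 without saline replicate 1 (0.0809) or 2 (0.0528).

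**Figure D1:**
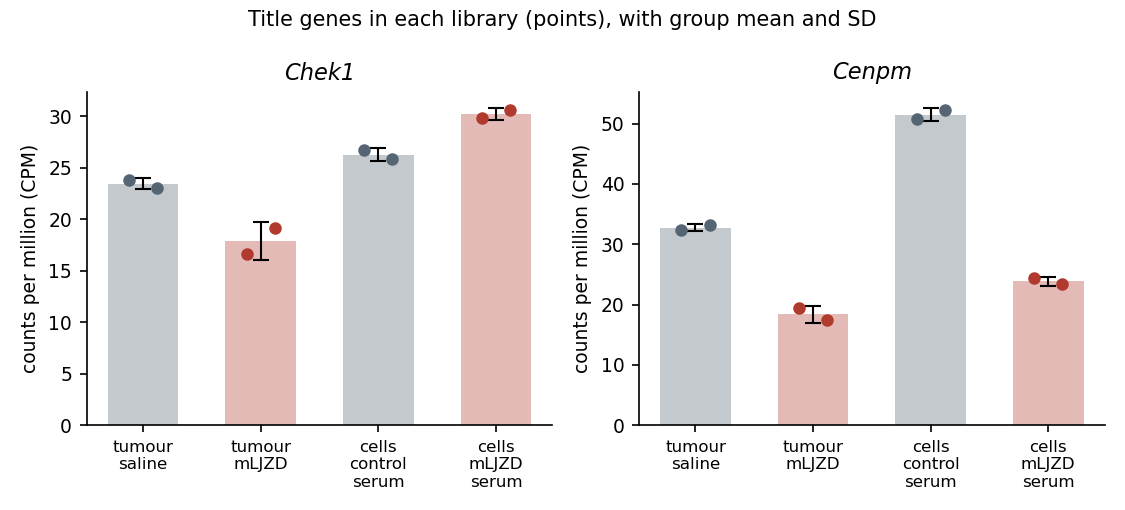
CPM of Chek1 and Cenpm (y axis) in the 4 groups (x axis); points are libraries, bars group means and error bars SD, n = 2. Cenpm was lower under mLJZD in tumours (18.4 against 32.7 CPM) and cultures (23.9 against 51.5 CPM), while Chek1 was lower in tumours (17.9 against 23.5 CPM) and stood at 30.2 against 26.3 CPM in cultures, a difference that did not pass the test. With the trend in transcript length and GC content removed, the log2 fold change of Cenpm in cultures was -0.51 in place of -1.17.

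In tumours, genes of DNA replication and cell division were lower under mLJZD. Of 40 genes of DNA replication and the G1/S transition, 32 fell and none rose, with a median log2 fold change of -0.33 (camera adjusted p = 1.67e-09; adjusted p = 0.20 with an estimated correlation). Among them were the helicase subunits Mcm6 (log2 -0.69, SE 0.05), Mcm3 (-0.68, SE 0.05) and Mcm2 (-0.56, SE 0.05) and the polymerase subunit Pola1 (-0.56, SE 0.05). Of 39 genes of G2 and mitosis, 30 fell and 1, Cdca8, rose (median -0.21, camera adjusted p = 3.57e-07; adjusted p = 0.20 with an estimated correlation), including Kif20b (-0.55, SE 0.05), Racgap1 (-0.44, SE 0.05) and the proliferation marker Mki67 (-0.38, SE 0.04). Of 33 centromere and kinetochore genes, 16 fell and none rose (median -0.25, camera adjusted p = 6.70e-05; adjusted p = 0.218 with an estimated correlation). Besides Cenpm these included Hjurp, the chaperone that loads the centromeric histone (-0.65, SE 0.05), and Cenpf (-0.64, SE 0.06). Of 29 genes of the ATR pathway and DNA repair, 16 fell and none rose (median -0.27, camera adjusted p = 0.000133; adjusted p = 0.279 with an estimated correlation), with Fanci (-0.80, SE 0.13), Brca1 (-0.55, SE 0.06) and Exo1 (-0.52, SE 0.13) among them. The replication-dependent histone genes, a list fixed beforehand as a mark of RNA selection, went the other way: of 11 tested, Hist1h1c (0.85, SE 0.10) and Hist1h2bc (0.79, SE 0.15) rose and none fell (median 0.79, camera adjusted p = 0.00560; adjusted p = 0.309 with an estimated correlation). This call ended without mLJZD replicate 1 (adjusted p = 0.0868), and histone gene copies can share reads. Adjusted over the list alone, 33 replication genes and 31 mitosis genes fell and the other counts were equal.

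Gene lists of hypoxia, the unfolded protein response, immediate early genes and inflammation were higher in the mLJZD tumours. The hypoxia and glycolysis list and the unfolded protein response and ATF4 list were each written as 29 symbols, which matched 30 gene identifiers. Counts of list members are counts of tested identifiers. Of 30 hypoxia and glycolysis genes, 28 rose and none fell (median 0.49, camera adjusted p = 3.08e-13; adjusted p = 0.20 with an estimated correlation). Car9, a carbonic anhydrase induced by hypoxia, rose from 4.79 ± 1.41 to 35.5 ± 0.71 CPM (log2 2.92, SE 0.14), and the glucose transporter gene Slc2a1 rose by 1.31 (SE 0.05). Of 29 genes of the unfolded protein response and ATF4, 18 rose and 1, Shmt2, fell (median 0.22, camera adjusted p = 2.80e-06; adjusted p = 0.20 with an estimated correlation), led by Chac1 (1.72, SE 0.08), Atf3 (1.53, SE 0.15), Trib3 (1.24, SE 0.06) and Ddit3 (1.08, SE 0.06). Of 18 immediate early genes, which also respond to the handling of tissue, 17 rose (median 0.74, camera adjusted p = 2.09e-10; adjusted p = 0.20 with an estimated correlation), with Egr1 at 1.43 (SE 0.04) and Dusp1 at 1.22 (SE 0.06). Of 24 NF-kB and inflammation genes, 14 rose and 3 fell (median 0.41, camera adjusted p = 0.000114; adjusted p = 0.349 with an estimated correlation), with the neutrophil chemokine genes Cxcl3 (2.45, SE 0.33), Cxcl2 (1.31, SE 0.29) and Cxcl5 (1.10, SE 0.31). Of 24 genes of TGF-beta, mesenchymal transition and invasion, 14 rose and 3 fell (median 0.20, camera adjusted p = 0.000468; adjusted p = 0.471 with an estimated correlation), with Ccn1 (1.35, SE 0.06) and Mmp3 (0.77, SE 0.12). Adjusted over the list alone, 16 of these rose and the counts of the other lists named here were equal.

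Ribosomal protein genes rose in 67 of 83 cases (median 0.28, camera adjusted p = 2.77e-13, or 0.518 with an estimated correlation). With the trend in length and GC described below for the cultures removed, 55 rose and 5 fell. The median was then 0.20 (camera adjusted p = 2.21e-07, or 0.622 with an estimated correlation). Before removal the only exception that fell was Rpl3l (-1.46, SE 0.34), a paralogue expressed in muscle. Rpl3l, Cdca8, Shmt2, Lgr6 and, among the muscle genes, Myh2 are named as exceptions to their lists and were picked after their values were seen. Of 24 p53 targets 11 rose and 4 fell (median 0.16, camera adjusted p = 0.0411; adjusted p = 0.649 with an estimated correlation). Plk3 (1.22, SE 0.08), Sesn2 (1.07, SE 0.06) and Plk2 (0.89, SE 0.05) moved most. Of 11 Wnt targets 6 rose and 1, Lgr6, fell (median 0.37, camera adjusted p = 0.0411; adjusted p = 0.352 with an estimated correlation). Leaving out mLJZD replicate 1 ended the calls for the p53 (adjusted p = 0.188) and Wnt lists (0.0874). So did leaving out saline replicate 2 for the p53 list (0.0945) and saline replicate 1 for the Wnt list (0.0577). Heat shock genes were split, with 7 of 16 higher and 6 lower and no list call (camera adjusted p = 0.451); Hspa1a rose by 2.02 (SE 0.16) and Hspa1b by 1.32 (SE 0.07), a pair that can share reads. Histone acetylation enzymes gave 4 higher and 5 lower of 26 (camera adjusted p = 0.878), with the acetyltransferase gene Ep300 at -0.36 (SE 0.06). Of the 13 mitochondrially encoded genes 9 fell (median -0.38, camera adjusted p = 0.00334; adjusted p = 0.502 with an estimated correlation), and these genes held 1.67% ± 0.08 of the counts in saline and 1.31% ± 0.12 in mLJZD tumours (SD, n = 2).

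Markers of other cell types moved apart in the same tumours. Skeletal muscle genes fell in 14 of 16 cases and 1 rose (median -2.19, camera adjusted p = 2.77e-13; adjusted p = 0.20 with an estimated correlation). The fast myosin gene Myh4 fell from 776 ± 6.94 to 71.0 ± 1.51 CPM, while Myh2, another fast myosin gene, rose from 9.60 ± 0.72 to 20.8 ± 2.18 CPM. The muscle list took 0.331% ± 0.00184 of the counts in saline tumours and 0.0611% ± 0.000423 in mLJZD tumours (SD, n = 2). Of 12 neutrophil genes 10 rose and none fell (median 1.42, camera adjusted p = 3.49e-08; adjusted p = 0.279 with an estimated correlation). The granule genes Mpo and Elane were absent from both saline libraries and at least 23.3-fold and 12.7-fold higher in mLJZD tumours, with the median unchanged when both were set to these bounds. Of 12 B and plasma cell genes 6 rose and none fell (median 1.51, camera adjusted p = 0.00190; adjusted p = 0.279 with an estimated correlation). Igkc, the kappa light chain constant region, rose from 19.1 ± 1.82 to 280.1 ± 21 CPM and Jchain from 6.38 ± 1.19 to 55.7 ± 3.27 CPM. All 5 tested erythroid genes rose (median 1.36, camera adjusted p = 0.000179; adjusted p = 0.349 with an estimated correlation). Few T cell (2 higher and 2 lower of 19) or endothelial genes (2 higher of 15) changed, while fibroblast genes moved both ways (5 higher and 3 lower of 18). None of these lists was called (camera adjusted p = 0.632, 0.582 and 0.632). The macrophage list was not called either (6 higher and 4 lower of 19, adjusted p = 0.984). Its members Cd163 (-1.80, SE 0.18) and Mrc1 (-0.66, SE 0.05), both receptors of tissue-resident macrophages, fell, while Trem2 (0.54, SE 0.10) and Ms4a7 (0.50, SE 0.09) rose. Adjusted over the list alone, 11 neutrophil and 7 B and plasma cell genes rose and the other counts were equal.

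**Figure D2:**
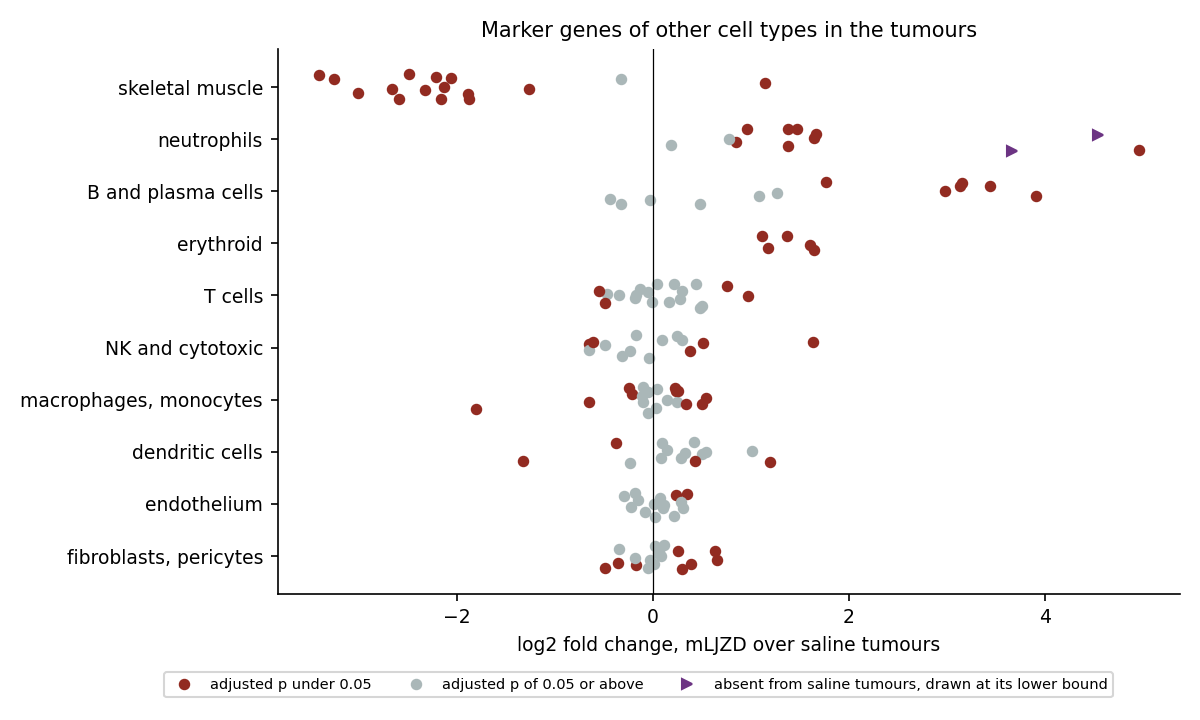
Log2 fold change in mLJZD over saline tumours (x axis) of each tested marker gene of 10 cell types (y axis), coloured by its edgeR adjusted p; triangles are lower bounds for genes absent from saline tumours. Skeletal muscle genes lie to the left (median -2.19) and neutrophil, B cell and erythroid genes to the right (medians 1.42, 1.51 and 1.36), while T cell, endothelial and fibroblast genes lie around 0.

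Over all genes, 4835 of 15417 tested changed in tumours, 2371 higher and 2464 lower, and 772 of them by at least 2-fold (edgeR adjusted p under 0.05). The share of higher genes among the calls was 49.0%, and 41.4% with library totals only. The 10 largest rises held 8 immunoglobulin V segments, 1 further segment annotated as a V pseudogene, and Mpo. Ighv3-8 was absent from saline libraries and at least 193-fold higher, Ighv1-52 at least 176-fold and Ighv4-1 at least 127-fold. Of 95 V segments with at least 20 counts, 12 were absent from both saline libraries. The 2 mLJZD libraries ranked the segments at a Spearman correlation of 0.91 across segments, which are not independent replicates, and the 2 saline libraries at 0.69, whereas the values between groups were 0.18 to 0.25. Of the 95 segments, 23 were absent from 1 library of a group and present in the other. The largest falls included the non-coding RNA gene Platr3 (-4.93, SE 0.49), Ucp3 (-4.53, SE 0.59), a mitochondrial carrier of muscle, Sh2d4a (-4.07, SE 0.29), the coagulation factor gene F5 (-3.89, SE 0.20) and Mylk4 (-3.61, SE 0.30). Ankef1 (-4.34), Rex2 (-4.13), Mt3 (-4.01), Gstp2 (-4.0) and Asb10 (-3.97) completed the 10. Without mLJZD replicate 1 the count of changed genes was 1087 and without mLJZD replicate 2 it was 1974, and 1083 and 1945 of these were among the 4835.

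In the cultures with mLJZD serum, log2 fold changes ran along transcript length. The median log2 fold change of protein-coding genes rose from -0.76 for transcripts under 1000 bases to 1.00 for those over 8000 bases, against 0.09 and -0.08 in tumours. Of the shortest group 76.0% fell and of the longest 82.9% rose. Over all genes, 7365 of 13299 tested changed, 3825 higher and 3540 lower, and 1466 of them by at least 2-fold (edgeR adjusted p under 0.05). The share of higher genes among the calls was 51.9%, and 71.3% among those of at least 2-fold; it turned to 42.0% with upper-quartile scaling and to 45.0% with all 8 libraries in one fit. With the trend in length and GC removed per library, an alternative chosen after seeing the data, 5109 genes were called. Of the original 7365 calls, 3772 stayed in the same direction (51.2%) and 240 turned. The removal was not complete at the ends. Protein-coding genes under 1000 bases kept a median of -0.20 after it, and those over 8000 bases 0.13. Every gene list of the cultures below is therefore given with its value after that removal, and so are its named members.

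**Figure D3:**
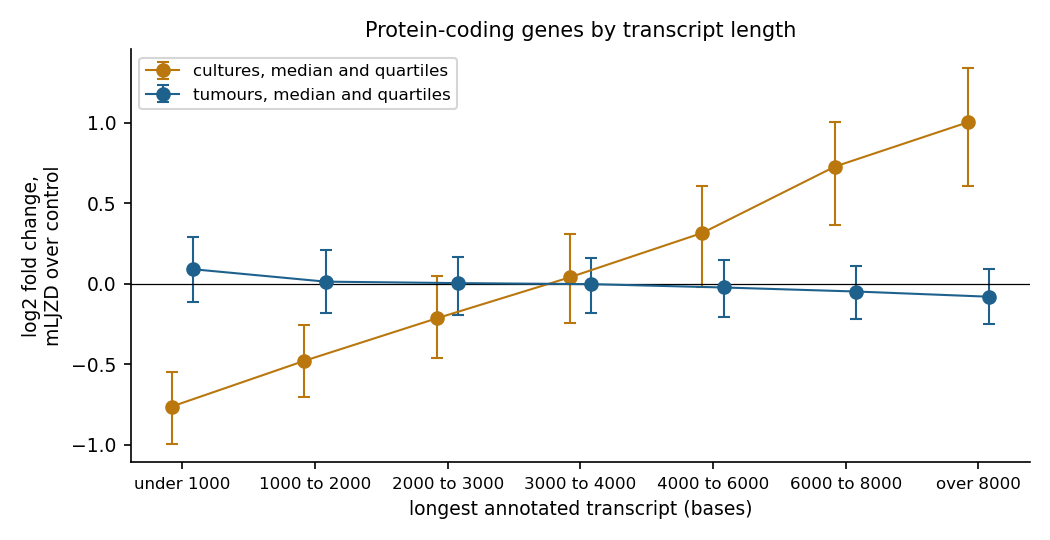
Median log2 fold change, mLJZD over control (y axis), of protein-coding genes grouped by their longest transcript (x axis, bases), in cultures and tumours; bars are quartiles over genes. The cultures rise from -0.76 under 1000 bases to 1.00 over 8000 bases, and the tumours stay between 0.09 and -0.08.

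Ribosomal protein genes fell in 77 of 82 cases in the cultures and none rose (median -0.82, camera adjusted p = 1.12e-16; adjusted p = 0.757 with an estimated correlation). With the trend removed 58 fell and 2 rose (median -0.39, camera adjusted p = 3.10e-11). Rpl31 (-1.38, SE 0.17), Rpl35 (-1.28, SE 0.10) and Rpl13 (-1.21, SE 0.08) moved most, and stood at -1.01, -0.56 and -0.86 after removal. Nuclear genes of oxidative phosphorylation fell in 23 of 28 cases and 2 rose (median -0.59, camera adjusted p = 9.61e-05; adjusted p = 0.757 with an estimated correlation), and in 16 with 5 higher after removal (median -0.26, adjusted p = 0.0149). Cox7a2 (-1.15, SE 0.18) and Cox5b (-1.04, SE 0.12), subunits of cytochrome c oxidase, were among them, at -0.61 and -0.60 after removal. Targets of NRF2, the regulator of antioxidant genes, fell in 13 of 22 cases and 3 rose (median -0.45, camera adjusted p = 0.0152; adjusted p = 0.757 with an estimated correlation), and 9 fell and 2 rose after removal (median -0.24, adjusted p = 0.0461). Gstm1 (-1.12, SE 0.10; -0.55 after removal) and Gstp1 (-0.97, SE 0.08; -0.28 after removal) led this list. Hypoxia and glycolysis genes fell in 19 of 28 cases and 4 rose (median -0.43, camera adjusted p = 0.0138; adjusted p = 0.757 with an estimated correlation), and 12 fell and 4 rose after removal (median -0.14, adjusted p = 0.0268). Car9 fell from 24.5 ± 1.18 to 11.5 ± 1.39 CPM (log2 -1.15; -0.73 after removal). Antigen presentation genes fell in 11 of 15 cases and 2 rose (median -0.56, camera adjusted p = 0.00566; adjusted p = 0.757 with an estimated correlation), and 6 fell and none rose after removal (median -0.18, adjusted p = 0.0131). The immunoproteasome genes Psmb9 (-2.18, SE 0.42), Psmb10 (-0.93, SE 0.12) and Psmb8 (-0.92, SE 0.23) and the invariant chain gene Cd74 (-1.69, SE 0.34) were the members that moved most. After removal Psmb9 (-1.94) and Cd74 (-1.05) stayed called, while the calls for Psmb10 (-0.27, edgeR adjusted p = 0.0643) and Psmb8 (-0.53, edgeR adjusted p = 0.0845) ended. Adjusted over the list alone, 78 ribosomal protein genes fell and 3 oxidative phosphorylation genes rose, and the other counts of these lists were equal.

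The list of the ATR pathway and DNA repair rose in 18 of 29 cases and fell in 2 in the cultures (median 0.45, camera adjusted p = 0.00167; adjusted p = 0.757 with an estimated correlation). Its call ended with the trend removed (13 higher, 3 lower, median 0.22, adjusted p = 0.0609). Atm, a kinase of the response to double-strand breaks with a long transcript, rose from 13.4 ± 2.50 to 86.8 ± 1.15 CPM (log2 2.64, SE 0.11; 1.66 after removal) and Atr by 1.54 (SE 0.10; 0.68 after removal). Interferon response genes rose in 16 of 32 cases and fell in 4 without a list call (median 0.45, camera adjusted p = 0.0846). After removal 18 rose and 1 fell and the list was called (median 0.38, camera adjusted p = 0.0267; adjusted p = 0.707 with an estimated correlation). Removal also brought calls for cholesterol synthesis (9 lower and 1 higher of 23, median -0.18, camera adjusted p = 0.0465) and the fibroblast list (3 lower of 9, median -0.42, camera adjusted p = 0.0497). All 8 lists called after removal had an adjusted p = 0.707 with an estimated correlation. Gbp5 (2.81, SE 0.59), Parp14 (1.44, SE 0.20) and Rsad2 (1.16, SE 0.15) rose, and stood at 2.71, 0.69 and 0.91 after removal. Cell division genes went both ways. Of 39 genes of G2 and mitosis 17 rose and 14 fell, of 40 replication genes 12 rose and 14 fell, and of 33 centromere and kinetochore genes 8 rose and 13 fell, with no list called (camera adjusted p = 0.553, 0.928 and 0.553). After removal 14 rose and 9 fell, 13 rose and 8 fell, and 3 rose and 9 fell, again with no list called (adjusted p = 0.743, 0.982 and 0.160). Mki67 (1.31, SE 0.07), Kif20b (1.09, SE 0.09) and Cenpe (1.11, SE 0.08) rose, while Cks2 (-1.0, SE 0.10), Ube2c (-0.91, SE 0.10) and Cenpx (-1.08, SE 0.12) fell. After removal all 6 stayed called with smaller changes, at 0.32, 0.53, 0.29, -0.63, -0.49 and -0.41. The acetyltransferase genes Ep300 (1.87, SE 0.09) and Kat6a (1.83, SE 0.09) rose in a list that was not called (10 higher and 5 lower of 26, camera adjusted p = 0.553), and stood at 1.06 and 0.93 after removal, when 6 members were higher and 4 lower (adjusted p = 0.713). Adjusted over the list alone, 19 repair, 18 mitosis and 13 replication genes rose, and the other counts were equal.

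The largest rises in the cultures were H60b, a ligand of the receptor NKG2D (3.84, SE 0.77), the antisense RNA gene Kcnq1ot1 (3.43, SE 0.25), the copper transporter gene Atp7a (3.24, SE 0.16) and Ankhd1 (3.12, SE 0.12). Ankrd42 (3.01), Pdpr (3.00), Tnk2os (3.00), Zfp442 (2.98), Lrch3 (2.85) and Sycp1 (2.84) followed. The largest falls were Hist1h2ae (-3.06, SE 0.58), Gdap1l1 (-3.03, SE 0.63), the selenium-binding protein gene Selenbp1 (-2.60, SE 0.36), Mmp23 (-2.53, SE 0.58) and the keratin gene Krt19 (-2.45, SE 0.57). Ccpg1os (-2.44), Ppm1n (-2.21), Psmb9 (-2.18), Clec11a (-2.13) and the circadian gene Dbp (-2.0) followed. Of these 20, 19 stayed called with the trend removed, and Ppm1n did not (-1.50, edgeR adjusted p = 0.0594); Kcnq1ot1 then stood at 2.18. Mitochondrially encoded genes held 1.07% ± 0.02 of the counts in control cultures and 0.870% ± 0.349 in mLJZD cultures (SD, n = 2). The spread in mLJZD cultures exceeded the difference between the means. Their replicate 1 stood at 0.623% and replicate 2 at 1.12%, above both control libraries (1.06% and 1.09%).

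The responses in tumours and cultures were compared directly, since both address mLJZD on the same line. Of 12694 genes tested in both, 999 changed in the same direction, against 1159 for independent lists, and 1684 in opposite directions, against 1161. Log2 fold changes correlated at Pearson -0.11 and Spearman -0.14 across genes, which are not independent replicates. With the trend removed the counts were 891 against 870 and 1149 against 858. The interaction called 7136 of 16090 genes, 3834 of them with a higher effect in tumours and 3302 with a lower one (edgeR adjusted p under 0.05), a split of 53.7% higher that turned with library totals only (39.7%) and with no filter on low counts (44.1%). Lists whose effect was higher in tumours included ribosomal proteins (median difference 1.18, 79 of 83 members, camera adjusted p = 3.41e-20; adjusted p = 0.255 with an estimated correlation) and hypoxia and glycolysis (0.97, 24 of 30 members, camera adjusted p = 3.80e-07; adjusted p = 0.166 with an estimated correlation). The ATR and repair list had a lower effect in tumours (median difference -0.69, 19 of 29 members, camera adjusted p = 6.60e-06; adjusted p = 0.166 with an estimated correlation). After removal of the trend these differences were 0.70 for ribosomal proteins (71 members), 0.90 for hypoxia and glycolysis (24 members) and -0.41 for ATR and repair (14 members), all still called (camera adjusted p = 3.86e-16, 5.79e-09 and 8.87e-05). With an estimated correlation their adjusted p = 0.206, 0.0813 and 0.115. The largest single differences were Akr1c18 (7.43, SE 0.97), Cd79a (6.64, SE 1.55), Cpn1 (6.31, SE 0.93), Slc39a4 (5.79, SE 1.46) and Cxcr2 (5.74, SE 2.02) upwards, and Sh2d4a (-7.00, SE 2.24), Cmya5 (-6.42, SE 1.86), Itga2 (-6.25, SE 1.26), Adcy9 (-6.07, SE 1.77) and Trpv4 (-6.04, SE 1.82) downwards. All 10 stood below 1 CPM in both culture groups, and 8 of them had no count in 1 of these groups, so these sizes rest on very few culture counts and are no bounds.

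**Figure D4:**
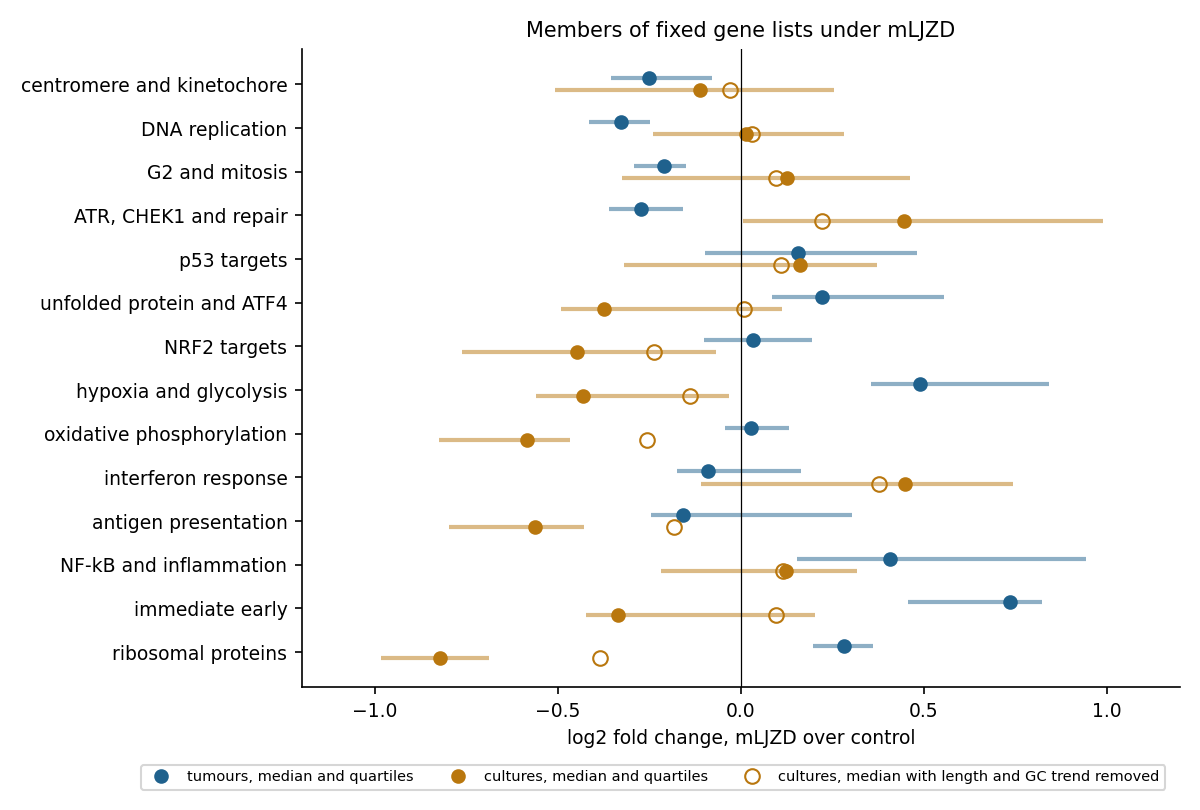
Median log2 fold change, mLJZD over control (x axis), of 14 gene lists (y axis) in tumours and cultures, with quartiles over members as bars and, as open circles, culture medians with the length and GC trend removed. Ribosomal protein and hypoxia genes lie above 0 in tumours (0.28 and 0.49) and below 0 in cultures (-0.82 and -0.43), and the ATR and repair genes the other way round (-0.27 and 0.45). With the trend removed these culture medians were -0.39, -0.14 and 0.22, and the ATR and repair list was no longer called in cultures.

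The saline tumours and the control cultures were set side by side to describe what the tumours hold beyond the cultured line. In this contrast 12357 of 15332 genes changed, 6879 higher and 5478 lower in tumours (edgeR adjusted p under 0.05). Every tested marker of T cells (19), macrophages and monocytes (19), endothelium (15), fibroblasts and pericytes (18), natural killer cells (14) and skeletal muscle (16) was higher. The camera adjusted p of these lists lay between 3.83e-08 and 1.67e-05, and the adjusted p between 0.160 and 0.229 with an estimated correlation. The muscle genes Acta1 and Myh4 were at least 11040-fold and 10542-fold higher, the lysosomal protease genes Ctsc and Ctss at least 6369-fold and 4939-fold, and the complement gene C1qa at least 4464-fold. Igsf11 was at least 104-fold lower in tumours, Ceacam10 at least 25.8-fold, Mogat2 at least 24.8-fold and mt-Ts2 at least 21.7-fold, and the laminin gene Lamb3 had a log2 fold change of -8.86 (SE 0.26). Interferon response genes were higher in tumours in 34 of 35 cases and antigen presentation genes in 20 of 20 (camera adjusted p = 1.86e-07 and 3.23e-07; adjusted p = 0.160 for both with an estimated correlation). NRF2 targets were lower in 21 of 22 cases (camera adjusted p = 3.86e-08; adjusted p = 0.160 with an estimated correlation). Cenpm (log2 -0.82, SE 0.07, edgeR adjusted p = 1.39e-06) and Chek1 (log2 -0.33, SE 0.09, edgeR adjusted p = 0.00653) were lower in saline tumours than in control cultures. The call for Chek1 ended with library totals only (adjusted p = 0.128) and without saline replicate 2 (0.0661). Host cells, growth in the animal and the serum of the cultures differ together in this contrast.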

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

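The tests of a length and GC trend as the whole cause of the culture calls and both tests on skeletal muscle were chosen only after the results they measure were seen, as was the removal of that trend; the other tests here were set out beforehand. Genes and lists below differed between tumours and cultures in a test of the interaction over all 8 libraries, with edgeR for genes and camera for lists, and each value is the effect in tumours minus that in cultures on the log2 scale.

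Of the title genes and those named for the size of their change, 33 differed; 22 of these had a mean below 1 CPM in tumours or cultures, and the 11 others are given here, a limit chosen after seeing the data. The title genes differed, Cenpm by 0.46 (edgeR adjusted p = 0.00635) and Chek1 by -0.42 (edgeR adjusted p = 0.0198). With the length and GC trend removed both missed the threshold, at -0.15 (0.378) and -0.25 (0.168), while the other 9 genes here kept their direction and their side of it, with Kcnq1ot1 at -2.08. Lower in tumours than in cultures by this measure were the effects on Atp7a (-3.49), Zfp442 (-3.44), Kcnq1ot1 (-3.32), Pdpr (-3.27), Ankhd1 (-3.16), Lrch3 (-3.13) and Sycp1 (-2.50). Higher were those on Selenbp1 (2.94) and Psmb9 (2.01). The edgeR adjusted p of these 9 genes ranged up to 7.75e-05. All 9 were named for being among the 20 largest changes in the cultures, and the same culture libraries enter the interaction. Their differences therefore largely repeat the culture changes, such as 3.24 for Atp7a, 3.43 for Kcnq1ot1 and -2.60 for Selenbp1. The choice favours large sizes, and the adjusted p does not allow for it.

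The interaction called 15 gene lists, of which 10 had at least 50% of their members at a mean of 1 CPM or more in both materials, the same limit for genes. Among these 10 the difference was positive for ribosomal proteins (median 1.18, camera adjusted p = 3.41e-20), immediate early genes (1.08, 7.20e-05), hypoxia and glycolysis (0.97, 3.80e-07), oxidative phosphorylation (0.79, 2.17e-05), the unfolded protein response and ATF4 (0.64, 7.56e-05), antigen presentation (0.51, 0.00433) and NRF2 targets (0.48, 0.00676). It was negative for the ATR pathway and repair (-0.69, 6.60e-06), G2 and mitosis (-0.28, 0.0290) and DNA replication (-0.19, 0.0144). With an estimated correlation the adjusted p of the lists called in the interaction lay between 0.166 and 0.255. Of the 10 lists, 9 stayed past the threshold with the trend removed, most with smaller medians, and antigen presentation did not (0.25, camera adjusted p = 0.115). The medians were then 0.70 for ribosomal proteins, 0.76 for immediate early genes, 0.90 for hypoxia and glycolysis, 0.40 for oxidative phosphorylation, 0.42 for the unfolded protein response and ATF4, 0.23 for NRF2 targets, -0.41 for the ATR pathway and repair, -0.25 for G2 and mitosis and -0.26 for DNA replication. The call for G2 and mitosis ended without tumour mLJZD replicate 2 (adjusted p = 0.0576). The other 5 lists had fewer members at that level: skeletal muscle (median -1.98, camera adjusted p = 2.17e-05), neutrophils (1.57, 7.43e-05), erythroid genes (1.37, 0.00772), B and plasma cells (0.94, 0.0223) and replication-dependent histones (1.99, 0.0223). With the trend removed the call for B and plasma cells ended (adjusted p = 0.0617), the other 4 stayed, and cholesterol synthesis (camera adjusted p = 0.00720) and interferon response (0.00932) were newly called. With an estimated correlation the adjusted p of the lists called after removal lay between 0.0813 and 0.332.

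In the cultures long transcripts were higher and short ones lower under mLJZD serum, and library-to-library variation in preparation is argued against, since the largest slope between replicates, per doubling of length, was 0.1313 of the smallest slope between groups. Whether a trend with length and GC is the whole cause of the calls cannot be told. Once it was removed 51.22% of the called genes stayed called in the same direction, and the other calls ended or turned. That share is close to the bound of 50%, which was set after the result was seen. The removal was also incomplete at both ends of the length range, so calls that stayed may hold leftover trend. For the ribosomal protein list, whose transcripts are short, the median after removal was -0.3853 (camera adjusted p = 3.10e-11). All protein-coding genes under 1000 bases still had a median of -0.203 then, so the removal was incomplete for short transcripts. Camera sets the list against genes of all lengths, so whether the trend is the whole cause of this fall cannot be told. A larger share of unspliced or nuclear RNA in the treated cultures may contribute. Sense intronic and antisense genes lay above protein-coding genes matched on length and level by a median of 0.3535, against 0.13 in tumours. Apart, the 23 sense intronic genes lay above by 1.26 and the 270 antisense genes by 0.33. Processed pseudogenes, which this explanation does not single out, lay above by 0.37. A difference in handling or RNA quality shared by both libraries of a group stays open, since the design confounds it with the serum, and so does an effect of the serum on RNA, which was not tested.

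Skeletal muscle genes were lower in mLJZD tumours. Whether a smaller share of muscle of a fixed composition is the cause cannot be told. The log2 fold changes of 14 muscle genes had an SD of 19.99 times their median SE, with Myh4 at -3.42 while Myh2 rose. That SE holds only the spread between libraries of a group, which may be technical, so a large ratio does not decide the question. A smaller share alone would not raise Myh2, but this is a single gene, picked after its value was seen. A smaller share of all host cells is argued against, since the lower of the endothelial and fibroblast medians was 0.03358. Muscle of different fibre composition or amount, as adjoining tissue taken with the tumour could bring, stays open and was not tested, and so does an effect of mLJZD.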

How the results depend on the processing

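The fits with the length and GC trend removed, with protein-coding genes only and with crossed replicate numbers were chosen after seeing the data; the others were planned. A threshold of 2-fold left 772 genes in tumours, 1466 in cultures and 6583 in the control contrast, as its construction requires. Other full sets of libraries gave 3287 (DESeq2) to 5411 genes in tumours, 5109 (trend removed) to 8213 in cultures, 9087 to 12567 in the control contrast and 5461 to 7215 in the interaction. Leaving out each library gave 1087 to 3536 genes in tumours, with 1087 without mLJZD replicate 1, 1974 without mLJZD replicate 2 and 3515 and 3536 without saline replicate 1 and 2. Of 164 named tumour calls 77 were lost without mLJZD replicate 1, 45 without mLJZD replicate 2 and 14 with DESeq2, and none reversed. Fewer libraries leave less to estimate the spread, and why the mLJZD libraries weigh more was not tested. In cultures the range was 6358 to 6889.

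Removing the length and GC trend in cultures reversed Chek1 (-0.054), Crebbp (-0.17), Slc7a11 (-0.19), Lgals9 (0.054), Apcdd1 (-0.36) and Mylk (-0.15), none of them past the threshold then. Of 125 named culture calls, which do not include Chek1, 35 ended, these 5 reversals and 30 in the same direction. It also reversed the difference for Cenpm (-0.15). These genes lost the part of their change that went with length and GC. No list was called with an estimated correlation: 0 in tumours, 0 in cultures and 0 in the difference of effects. With the trend removed as well, a pairing added after seeing the data, it was again 0 in each. This test also missed a simulated shift, but the simulated genes varied independently, which leaves open whether the preset correlation suits the data. Fry called 23 lists in tumours, 16 in cultures against 6, and 31 in the difference against 15; it asks another question.

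With library totals only, 39.7% of the interaction calls were higher against 53.7%, and the median of all genes was -0.09 against 0.07. The median moved to -0.12 with upper-quartile scaling in cultures and from 0.15 to 0.31 (totals only) or 0.43 (no filter) in the control contrast. The counts gave no sign that the replicate numbers pair the libraries, since deviations of same-numbered libraries correlated at -0.106 in tumours and 0.0226 in cultures. With 2 libraries per group this cannot exclude a pairing. With a replicate block 4461 genes were called in tumours, 7343 in cultures and 7024 in the interaction, and with crossed numbers 5411 in tumours. The block ended the list calls for p53 (adjusted p = 0.0640) and Wnt targets (0.0648) in tumours and for G2 and mitosis (0.0580) in the interaction. Depth set little: thinning to the lowest total left 4666 genes in tumours and 7097 in cultures.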

Other observations

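The test on V segments and its bounds were set out before its result was seen, its value was computed anew afterwards to take out counting noise as set out, and the pattern itself was noticed in these data; the genes here come from the lists fixed beforehand. Several lists without a call in tumours held single genes that changed. The keratin genes Krt8 (log2 -3.11) and Krt18 (-2.96) fell in mLJZD tumours, while Cdh17, an intestinal cadherin gene, rose (1.48), and the colon epithelium list was not called (3 lower and 1 higher of 5, camera adjusted p = 0.0633). Among checkpoint genes Ctla4 rose (1.45) and Tigit (-1.11) and Pdcd1 (-0.94) fell (5 higher and 3 lower of 13, camera adjusted p = 0.888). The class II genes H2-Aa (0.56), H2-Eb1 (0.55) and H2-Ab1 (0.51) rose in an antigen presentation list that had 5 higher and 10 lower of 20 (camera adjusted p = 0.661). Nqo1 (-1.29) and Aldh3a1 (-1.60), targets of the aryl hydrocarbon receptor, fell (1 higher and 2 lower of 6, camera adjusted p = 0.782). Adipocyte genes fell in 2 of 4 cases, Cfd (-3.08) and Car3 (-1.23), with a list call (camera adjusted p = 0.0237; adjusted p = 0.349 with an estimated correlation) that ended without mLJZD replicate 1 (0.0874).

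In cultures, genes of fatty acid synthesis were higher in 8 of 15 cases and lower in 2 without a list call (camera adjusted p = 0.12), and with the length and GC trend removed, a setting chosen after seeing the data, 3 were higher and 3 lower (median 0.51 before and 0.092 after, camera adjusted p = 0.757). Genes of the unfolded protein response and ATF4 fell in 17 of 28 cases and rose in 6 (median -0.37, camera adjusted p = 0.105), among them Ddit3 (-1.14), which rose by 1.08 in tumours. With the trend removed 7 fell and 8 rose (median 0.0089, mean -0.0048, camera adjusted p = 0.829), and Ddit3 still fell (-0.77).

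Immunoglobulin V segments ranked alike in the 2 libraries of the mLJZD tumours (Spearman 0.91 over 95 segments) and less so in those of the saline tumours (0.69, and 0.43 over the 16 segments with at least 20 counts there). If the libraries were made from separate tumours, V segments should differ more between them than other genes do, since each animal has its own B cell repertoire. Beyond counting noise they varied 2.474 times as much as other genes of the same level in saline tumours, on 16 segments, and 0.639 times as much in mLJZD tumours, on 90 segments. The values first computed, with counting noise left in, were 1.55 and 0.827, both under the bound of 2 set beforehand for the same tumour material, so taking the noise out changed the verdict. The verdict rested on the higher value, that of the saline tumours on 16 segments. This value now lies between that bound and the bound of 3 for separate tumours, so for the saline tumours these cannot be told apart. In the mLJZD tumours V segments varied no more than other genes of the same level (0.639 times as much). The test set out beforehand took the higher of the 2 groups, so no verdict is drawn for the mLJZD tumours alone. Pooled animals were not tested.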
